A study of Saccharomyces cerevisiae with 5 samples.

How the data were processed

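Polyadenylated RNA of Saccharomyces cerevisiae was compared on 5 two-colour oligonucleotide arrays, with 1 array for each comparison and no replicate. Per the labels, cells grew to log phase in synthetic complete medium, and the stressed cultures received 0.4 mM hydrogen peroxide or 0.4 M KCl for 20 min. On 3 arrays a strain lacking SIW14 was compared with its wild type BY4741, either with no stress, with both strains in peroxide or with both in KCl. On the other 2 arrays a wild-type strain that the labels name differently (ACY044) was compared in peroxide or in KCl with its own unstressed cells. The labels give the Cy5 dye to the mutant or the stressed cells and the Cy3 dye to the wild type or unstressed cells on every array, with no dye swap, so that a dye effect and the compared difference cannot be separated. For the 2 arrays of stressed mutant cells, the source name of the Cy3 channel gives only the medium while its treatment entry gives the stress, and the treatment entry was followed.

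The values were the authors' deposited log ratios, 1 per probe and array, and no intensities, background levels or spot flags were used here. The deposited values were read as log2 of Cy5 over Cy3 per the labels' dyes, although the base is not given in the sources used here. Base 10 was ruled out because the highest value, 9.69, exceeds the largest base-10 ratio of 4.82 that a 16-bit scanner can give, whereas natural logarithms were not ruled out. The background correction, the normalisation and the cause of missing values are likewise not given in the sources used here. Array medians lay between -0.02 and 0.03, which leaves open whether the values were centred. Missing values made up 10.4% of probes for the unstressed mutant, 3.13% for wild type in peroxide, 1.63% for wild type in KCl, 7.13% for the mutant in peroxide and 6.94% for the mutant in KCl. Among unnamed probes of the unstressed mutant array the share missing was 23.1%, against 3.58% of named ones. No signal over background was at hand, so the number of arrays limits the precision and no error could be given for a single gene.

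Of 6256 yeast probes, 4075 had 1 gene symbol in the platform's annotation, 0 had several and 2181 had none. Of these symbols 3942 were current in the RefSeq gene table, 129 were updated through its synonyms and 4 were kept as given. Probes of the same gene were averaged, which applied to 7 symbols and left 6249 values per array, for 4068 named genes and the unnamed probes. The 53 control features were kept out of all counts and comparisons. No genome coordinates are given, since the build behind the array is not named in the sources used here.

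Because each comparison had 1 array, no test across replicates was possible, no p-value is given and no difference has a replicate check. Genes were counted as higher or lower at 2-fold or more, a log2 ratio of 1 in size, which is a rule of size and not a test. Before the data were examined, 28 gene lists were fixed from general knowledge of yeast. They covered general stress genes of the Msn2/Msn4 type, osmotic stress, peroxide defence, chaperones, proteasome, and trehalose and glycogen. Others covered ribosome biogenesis, RNA polymerases I and III, cytosolic and mitochondrial ribosomal proteins, histones, and G1/S and G2/M cell cycle genes. Metabolic lists covered respiration and the TCA cycle, glycolysis and fermentation, gluconeogenesis and fatty acid oxidation, hexose transporters, amino acid synthesis, sulphur and methionine, phospholipid synthesis, phosphate starvation, inositol phosphate metabolism and iron uptake. The remaining lists covered MATa-specific, MATalpha-specific, pheromone response, meiosis and sporulation, and auxotrophic marker genes. Several genes stand in more than 1 list. Each list is described by its median with an order-statistic 95% interval over its members, which covers the spread of genes and not of cultures. The median was also placed among those of 10000 random lists of equal size. Random lists could not be matched on expression because no intensities were used. A list is said to stand apart when its median fell below the 2.5 or above the 97.5 percentile. Lists of 20 drawn at random from each array's own values stood apart in 3.75% to 7.5% of draws, a rate that the rule itself sets. That rate need not hold for lists of genes that move together. After a shift by a log2 ratio of 1, at least 99.5% of the drawn lists stood apart.

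The genes named were chosen by a fixed rule: on each array the 12 named genes with the highest and the 12 with the lowest ratio, SIW14, MSN2 and MSN4, and in each list the 2 highest and 2 lowest members. For the mutant's response under stress, each stressed mutant array was set against the unstressed mutant array by subtraction, and the 8 highest and 8 lowest genes were named. Not every gene that this rule takes is reported here, and list members are named only in part. Genes named outside this rule were chosen after their values were seen. Correlations are Pearson's r across genes, which are not independent replicates. The 2 wild-type arrays could share their unstressed RNA, so r was also simulated for unchanged RNA with a shared control, and overlaps are given with the number independent lists would share. The alternatives tried were thresholds of 1.5-fold, 3-fold and 3 robust standard deviations, centring, scaling to the median absolute deviation, subtraction of chromosome medians, genes with a standard name or with values on all 5 arrays, other ways of combining probes or list members, and Spearman correlation. Reading the values as natural logarithms, drawing random lists from named genes and adding 2 gene groups were chosen after seeing the data. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.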

Results

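The data hold log2 ratios of 5 arrays that set yeast lacking SIW14, which encodes an inositol pyrophosphate phosphatase, against wild-type cells with and without stress, and wild-type cells under stress against unstressed ones. The comparisons address how loss of SIW14 bears on the environmental stress response, the shared programme in which stress genes turned on by Msn2 and Msn4 go up while genes for making ribosomes go down. A value was present for 5607 probes on the unstressed mutant array, 6060 for wild type in peroxide, 6154 for wild type in KCl, 5810 for the mutant in peroxide and 5822 for the mutant in KCl. Every comparison rests on 1 array, so no difference has a replicate check, and all values are log2 ratios unless stated.

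SIW14 itself lay at -2.07 in the unstressed mutant against wild type, at -1.66 with both strains in peroxide and at -2.06 with both in KCl. In wild-type cells it lay at 0.28 in peroxide and -0.22 in KCl, so the gene was low only on the arrays whose labels name the deletion. Where its probe lies relative to the deleted part is not given in the sources used here. Its chromosomal neighbours HHT2, HHF2 and KTR5 lay at 0.23, -0.05 and -0.02 in the unstressed mutant. MSN2 lay at 0.09 in the unstressed mutant and MSN4, which encodes its partner activator, was 2.78-fold higher.

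Unstressed siw14 cells had stress genes well above the wild type, while ribosome biogenesis genes lay slightly below it. Of the 53 general stress genes with a value, 43 were at least 2-fold higher and 0 at least 2-fold lower, with a median of 1.83 (95% interval over genes 1.61 to 2.27). DDR2, a multi-stress response gene, lay at 4.79, or 27.7-fold, GPH1, which encodes glycogen phosphorylase, at 4.28, SOL4, a 6-phosphogluconolactonase gene, at 4.19 and HOR7, a gene induced by osmotic stress, at 3.86. The small heat shock protein gene HSP26 lay at 3.44, the hexokinase gene HXK1 at 3.52, the glutamate decarboxylase gene GAD1 at 3.17, and the cell wall and stress genes SPI1, YGP1 and MSC1 at 3.75, 3.23 and 3.20. Ribosome biogenesis genes had a median of -0.25 (-0.33 to -0.19), with 87 of 101 below 0 and 0 at 2-fold or more, and stood apart, whereas cytosolic ribosomal protein genes had a median of 0.00 and did not.

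Several carbon and energy lists were also higher in the unstressed mutant. Trehalose and glycogen genes, of which 12 also stand in another list, had a median of 1.60 (0.99 to 1.90), with 14 of 20 at least 2-fold higher, among them the phosphatase regulator GAC1 at 2.89. Respiration and TCA cycle genes had a median of 1.05 (0.83 to 1.16), with 25 of 45 at least 2-fold higher, led by SDH2 of succinate dehydrogenase at 1.67 and QCR10 of the cytochrome bc1 complex at 1.66. Hexose transporter genes went both ways: the high-affinity transporter genes HXT7, HXT6 and HXT4 lay at 3.82, 3.41 and 2.87, but HXT2, also of high affinity, at -0.96, and the low-affinity genes HXT1 and HXT3 at -0.40 and -0.44. HXT6 and HXT7 are nearly identical in sequence, so their probes may not tell them apart. Osmotic stress genes had a median of 1.07 (0.29 to 2.04), with 8 of 14 at least 2-fold higher, but several of these are also general stress genes. Gluconeogenesis and fatty acid oxidation genes stood apart at a median of 0.32 (-0.79 to 1.5), with 3 of 11 at least 2-fold higher, including ICL1 of the glyoxylate cycle at 1.76. Mitochondrial ribosomal protein genes also stood apart, at 0.25 (0.17 to 0.33), with 0 of 45 at 2-fold or more.

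Metal uptake genes were among the lowest in the unstressed mutant. Iron uptake genes had a median of -0.95 (-1.77 to -0.58), with 8 of 17 at least 2-fold lower. FIT3 and FIT2, which encode cell wall proteins that retain iron siderophores, lay at -2.43 and -2.24, the siderophore transporter genes SIT1 and ENB1 at -2.28 and -1.83, the ferric reductase family genes FRE5 and FRE4 at -2.55 and -2.17, and TIS11, whose product degrades mRNAs of iron-using proteins, at -1.77. ZPS1, a zinc-regulated cell surface gene, had the lowest ratio of any named gene at -3.69, and the zinc-regulated alcohol dehydrogenase gene ADH4 lay at -2.45. SPO77 and SNO1 lay at -1.84 and -1.74.

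Most other lists of the unstressed mutant did not stand apart. Their medians were -0.18 for RNA polymerases I and III, -0.02 for peroxide defence, -0.06 for chaperones, 0.02 for the proteasome, 0.02 for phosphate starvation, -0.17 for inositol phosphate metabolism including SIW14, -0.03 for phospholipid synthesis, 0.16 for glycolysis and fermentation, 0.13 for hexose transporters, -0.10 for amino acid synthesis and -0.09 for sulphur and methionine. They were 0.27 for histones, -0.01 for both G1/S and G2/M genes and 0.16 for meiosis and sporulation. Of these only histones stood apart when random lists drew on named genes alone, at percentile 97.6. MATa-specific, MATalpha-specific, pheromone response and auxotrophic marker genes stood apart at 0.48, 0.79, 0.33 and 0.51. In all, 346 of 5603 genes were at least 2-fold higher and 87 lower, so 79.9% of these were higher, against 64.1% after each array was scaled to its own spread. The 3 E1A control features with a value on this array, which are not yeast genes, had a median of 2.08, above that of the general stress list.

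Wild-type cells in peroxide had stress and antioxidant genes higher and ribosome biogenesis genes lower than unstressed cells. General stress genes had a median of 2.23 (1.79 to 2.58), with 47 of 54 at least 2-fold higher, and peroxide defence genes a median of 1.54 (0.64 to 2.04), with 13 of 25 at least 2-fold higher and 1 lower. The glutathione peroxidase gene GPX2 lay at 4.22 and the thiol peroxidase gene AHP1 at 3.86. DDR2 lay at 5.43, SOL4 at 4.26, the heat shock genes HSP30, HSP42 and HSP26 at 5.65, 4.07 and 3.76, the sorbitol dehydrogenase gene SOR1 at 5.98, the dihydroxyacetone kinase gene DAK2 at 4.84, the glyceraldehyde-3-phosphate dehydrogenase gene TDH1 at 4.46 and the methyltransferase gene TMT1 at 3.78. Ribosome biogenesis genes had a median of -1.66 (-1.80 to -1.56), with 92 of 101 at least 2-fold lower, among them UTP20 and PWP2 at -3.48 and -3.17, and the helicase gene DHR2, outside the list, lay at -3.05.

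Iron uptake genes were higher in wild-type cells in peroxide, with a median of 1.72 (0.72 to 3.45) and 11 of 17 at least 2-fold higher, FIT2 lying at 5.45. Chaperone, proteasome, and trehalose and glycogen genes had medians of 1.07, 0.998 and 1.28, osmotic stress genes 1.5, and glycolysis and fermentation genes 1.98 (0.52 to 2.18), with 10 of 17 at least 2-fold higher. Amino acid synthesis and mitochondrial ribosomal protein genes stood apart at 0.43 and 0.56. Probes for open reading frames in mitochondrial introns had some of the lowest ratios, with AI1, AI2, AI4 and AI5_BETA at -4.99, -4.47, -3.53 and -3.46. The CTP synthase gene URA7 lay at -3.92, the aminopeptidase gene AAP1 at -3.91, the glutamate synthase gene GLT1 at -3.84, the adenine deaminase gene AAH1 at -3.02 and the sphingolipid synthesis gene AUR1 at -2.92.

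Further lists that stood apart below 0 in wild-type cells in peroxide were RNA polymerases I and III at -1.35, hexose transporters at -1.64, histones at -1.38, G2/M genes at -1.29, phosphate starvation at -0.91, G1/S genes at -0.79, and respiration and TCA cycle at -0.30. Intervals spanned 0 for hexose transporters (-2.48 to 0.55), G1/S genes (-1.49 to 0.28), and respiration and TCA cycle (-0.63 to 0.24). Of the 46 respiration and TCA cycle genes, 17 lay above 0, with 4 at least 2-fold higher and 9 at least 2-fold lower. The lists that did not stand apart were cytosolic ribosomal proteins at -0.04, inositol phosphate metabolism at -0.05, phospholipid synthesis at -0.49, gluconeogenesis and fatty acid oxidation at 0.22, sulphur and methionine at 0.33, MATa-specific at -0.46, MATalpha-specific at 0.01, pheromone response at -0.07, meiosis and sporulation at 0.42 and auxotrophic markers at 0.69. In all, 648 of 6053 genes were at least 2-fold higher and 687 lower.

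Wild-type cells in KCl had osmotic and general stress genes far above the unstressed level. All 14 osmotic stress genes with a value were at least 2-fold higher, with a median of 4.50 (2.22 to 6.37), and 49 of 50 general stress genes were, with a median of 3.79 (2.88 to 4.28). HSP12, a membrane-associated stress protein gene, lay at 9.69, the cytosolic catalase gene CTT1 at 8.02, the aldehyde dehydrogenase gene ALD3 at 7.55 and DDR2 at 7.43. STL1, which encodes a glycerol importer, lay at 6.68 and GPD1, for glycerol-3-phosphate dehydrogenase in glycerol synthesis, at 6.02. SIP18 and GRE1, both genes of desiccation and osmotic stress, lay at 6.37 and 5.57, the transketolase gene TKL2 at 6.15, and SOL4, PHM7 and SPI1 at 5.83, 5.82 and 5.67.

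Ribosome biogenesis genes in wild-type cells in KCl had a median of -2.71 (-3.01 to -2.51), with 99 of 101 at least 2-fold lower. The nucleolar genes NSR1, NOG1, PUF6 and NOP15 lay at -4.74, -4.31, -4.13 and -4.04, the RNA polymerase I gene RPA43 at -4.20, and URA7 at -4.02. MAK16, NOC2, EBP2, NAN1, UTP4 and RRP5, all needed to make ribosomes, lay between -3.88 and -3.71. RNA polymerase I and III genes had a median of -1.94, with 18 of 20 at least 2-fold lower, and cytosolic ribosomal protein genes a median of -0.27, with 20 of 128. Phosphate starvation genes had a median of -1.30 (-2.37 to -1.04), with 12 of 15 at least 2-fold lower, among them the phosphate transporter gene PHO84 at -3.56.

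Medians of the other lists that stood apart in wild-type cells in KCl were 2.43 for trehalose and glycogen, 1.30 for hexose transporters, 1.17 for glycolysis and fermentation, 0.90 for gluconeogenesis and fatty acid oxidation, 0.88 for chaperones, 0.82 for respiration and TCA cycle, 0.74 for iron uptake and 0.68 for the proteasome. Lower ones were -1.07 for sulphur and methionine, -0.91 for G1/S genes, -0.74 for G2/M genes and -0.70 for amino acid synthesis. Hexose transporter genes went both ways, with 4 of 7 at least 2-fold higher and 3 at least 2-fold lower. Peroxide defence genes did not stand apart, with a median of 0.19, nor did inositol phosphate metabolism at -0.03, phospholipid synthesis at 0.11, histones at 0.06, mitochondrial ribosomal proteins at 0.06, MATa-specific at -0.58, MATalpha-specific at -0.04, pheromone response at 0.01, meiosis and sporulation at 0.11 and auxotrophic markers at -0.20. In all, 707 of 6147 genes were at least 2-fold higher and 717 lower.

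**Figure D1:**
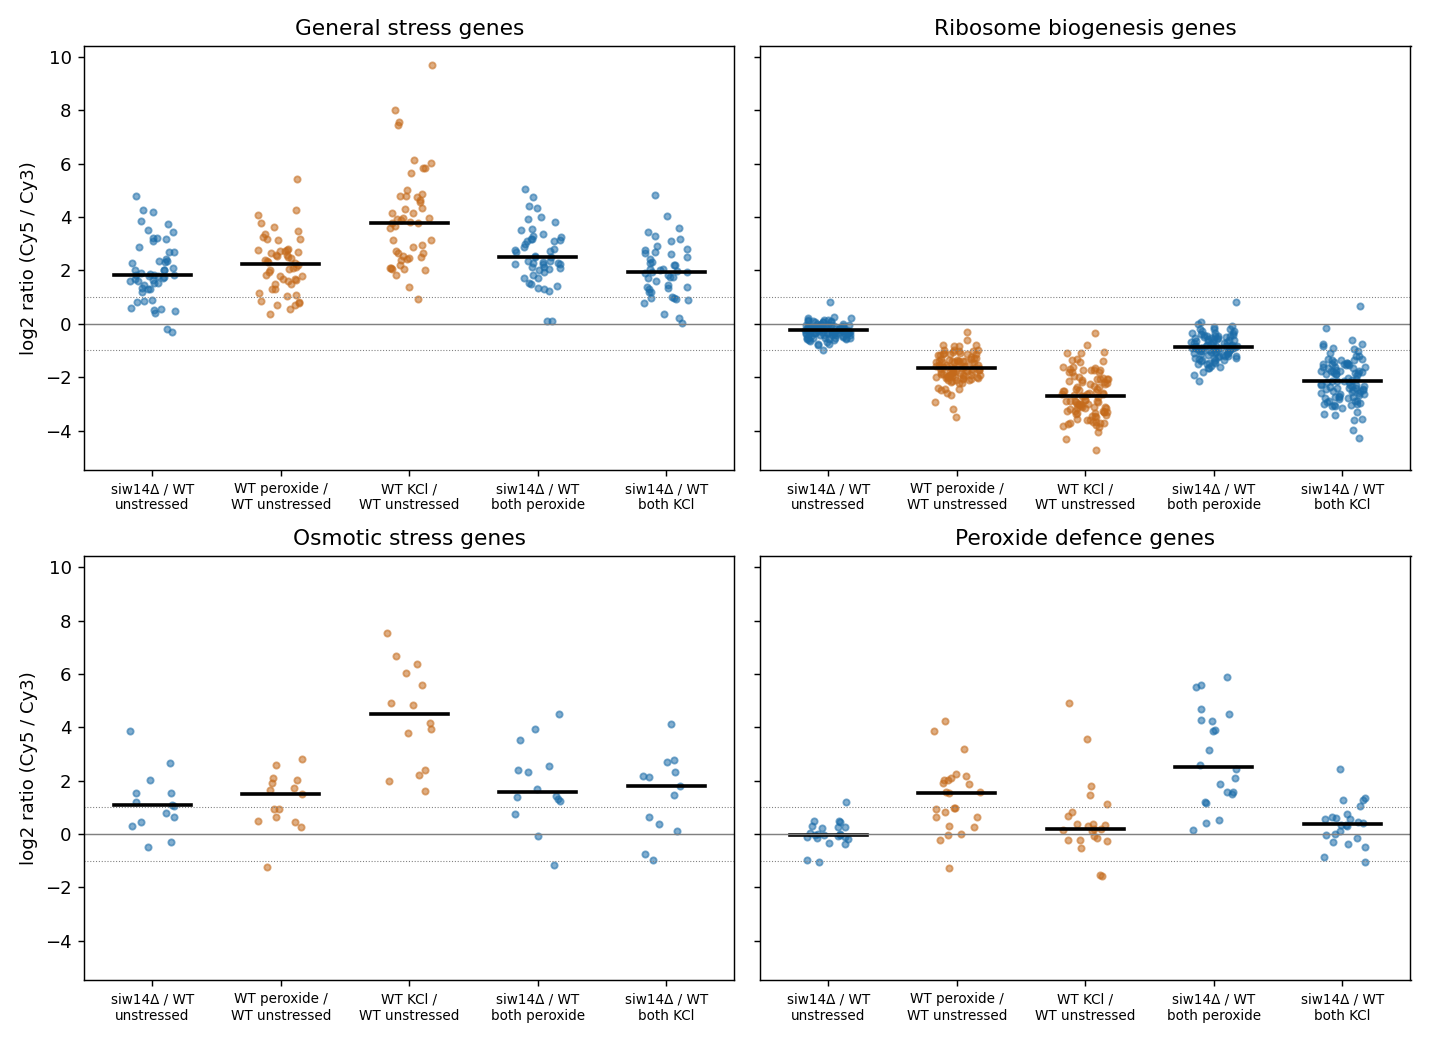
Log2 ratios (vertical axis, Cy5 over Cy3) of the genes in 4 lists on the 5 arrays (horizontal axis), with 1 point per gene, a black line at the median, blue for mutant arrays and orange for wild-type arrays, and dotted lines at 2-fold. General stress genes had medians from 1.83 to 3.79 on all 5 arrays, whereas ribosome biogenesis genes lay near 0 only in the unstressed mutant, at -0.25.

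With both strains in peroxide, siw14 cells had peroxide defence genes above the wild type. Peroxide defence genes had a median of 2.52 (1.5 to 4.26), with 19 of 22 at least 2-fold higher, and 3 others had no value. Over these 22 genes, wild type in peroxide against unstressed cells had a median of 0.99, whereas it was 1.54 over all 25. The NADPH oxidoreductase gene OYE3 lay at 5.90, the nitroreductase family gene FRM2 at 5.57, the glutathione transferase genes GTT2 and ECM4 at 5.51 and 4.83, the peroxiredoxin gene TSA2 at 4.69, the methylglyoxal reductase gene GRE2 at 4.49 and the drug exporter gene FLR1 at 4.26. General stress genes had a median of 2.49 (2.24 to 2.86), with 49 of 51 at least 2-fold higher, including HSP12 at 5.03, CTT1 at 4.76, SOL4 at 4.43 and MSC1 at 4.32. ECM13 lay at 4.40. The 7 E1A control features with a value on this array had a median of 1.17, with 1 below 0.

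Cell cycle and ribosome biogenesis genes were lower in siw14 cells than in wild type in peroxide. G1/S genes had a median of -1.16 (-1.85 to -0.95), with 9 of 12 at least 2-fold lower and the cyclin gene PCL1 at -3.40, and G2/M genes a median of -1.29, with 5 of 7. The cell cycle repressor gene YOX1 and the bud neck kinase gene KCC4 each lay at -2.53. Ribosome biogenesis genes had a median of -0.89 (-0.98 to -0.82), with 39 of 101 at least 2-fold lower, and RNA polymerase I and III genes a median of -0.85. SPO74 and SPS4, genes of sporulation, lay at -3.93 and -3.48, the cell wall gene DAN1 at -2.90, the hexose transporter family gene HXT11 at -2.60 and the branched-chain amino acid gene ILV5 at -2.59. ZPS1, the zinc regulator gene ZAP1 and ADH4 lay at -3.07, -2.70 and -2.49, and FRE4 at -2.57.

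Respiration and TCA cycle genes had a median of 1.08 in siw14 cells against wild type in peroxide, with 28 of 46 at least 2-fold higher, and trehalose and glycogen genes 1.96, with 17 of 20. Other lists that stood apart were osmotic stress at 1.56, glycolysis and fermentation at 1.0, gluconeogenesis and fatty acid oxidation at 0.77, mitochondrial ribosomal proteins at 0.55, the proteasome at 0.37 and cytosolic ribosomal proteins at -0.34. Lists that did not were chaperones at 0.34, which did at percentile 97.8 among random lists of named genes, hexose transporters at 0.58, iron uptake at 0.09, phosphate starvation at -0.26, inositol phosphate metabolism at -0.23, phospholipid synthesis at -0.40, amino acid synthesis at 0.16, sulphur and methionine at 0.03, histones at -0.52, MATa-specific at -0.36, MATalpha-specific at 0.54, pheromone response at 0.02, meiosis and sporulation at 0.03 and auxotrophic markers at 0.60. In all, 746 of 5806 genes were at least 2-fold higher and 482 lower, or 623 and 306 after each array was scaled to its own spread. MSN2 and MSN4 lay at 0.30 and 0.45.

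With both strains in KCl, siw14 cells had ribosome biogenesis genes below the wild type. Their median was -2.15 (-2.39 to -1.86), with 93 of 101 at least 2-fold lower. The helicase gene DHR2 lay at -5.50 and the ribosome assembly genes SSF1, NOC2, LTV1, NSR1, PWP2, HCA4 and NAN1 between -4.28 and -3.39. Cytosolic ribosomal protein genes had a median of -0.86 (-0.98 to -0.72), with 53 of 132 at least 2-fold lower, and RNA polymerase I and III genes a median of -1.28, with 16 of 20. URA7 lay at -3.92, the zinc transporter gene ZRT1 at -4.17, the phosphate transporter gene PHO84 at -3.49 and ZPS1 at -3.45.

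Stress genes were higher in siw14 cells than in wild type in KCl. General stress genes had a median of 1.95 (1.61 to 2.28), with 39 of 47 at least 2-fold higher; 7 of the 54 on the array had no value, among them CTT1, HSP12 and GPH1. DDR2 lay at 4.84, SIP18 at 4.12, TDH1 and GAC1 each at 4.04, HSP26 at 3.60 and the stress gene YRO2 at 3.67. The external NADH dehydrogenase gene NDE2 lay at 3.91, the glutathione peroxidase gene GPX1 at 3.89, the cell wall gene PIR3 at 3.79, SPG1 at 3.51 and the peroxisomal thiolase gene POT1 at 3.49. Osmotic stress genes had a median of 1.81 (0.11 to 2.69), with 8 of 13 at least 2-fold higher, but STL1 and GPD1 lay at 0.11 and 0.37. The 9 E1A control features with a value on this array had a median of 0.98, with 3 below 0.

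Other lists that stood apart in siw14 cells against wild type in KCl were G1/S genes at -1.30, with 11 of 12 at least 2-fold lower, hexose transporters at 1.63, trehalose and glycogen at 1.18, respiration and TCA cycle at 1.15, gluconeogenesis and fatty acid oxidation at 1.14, glycolysis and fermentation at 0.98, meiosis and sporulation at 0.63, chaperones at 0.39, peroxide defence at 0.38, mitochondrial ribosomal proteins at 0.37, iron uptake at -0.65 and amino acid synthesis at -0.36, the last not among random lists of named genes. Those that did not were G2/M genes at -0.40, the proteasome at 0.01, phosphate starvation at 0.13, inositol phosphate metabolism at 0.06, phospholipid synthesis at -0.11, sulphur and methionine at -0.20, histones at -0.07, MATa-specific at -0.45, MATalpha-specific at 0.64, pheromone response at -0.15 and auxotrophic markers at 0.67. Of the 7 hexose transporter genes, 4 were at least 2-fold higher and 1 at least 2-fold lower. In all, 663 of 5816 genes were at least 2-fold higher and 639 lower, but 357 and 462 among genes with a standard name. MSN2 and MSN4 lay at 0.01 and 0.80.

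**Figure D2:**
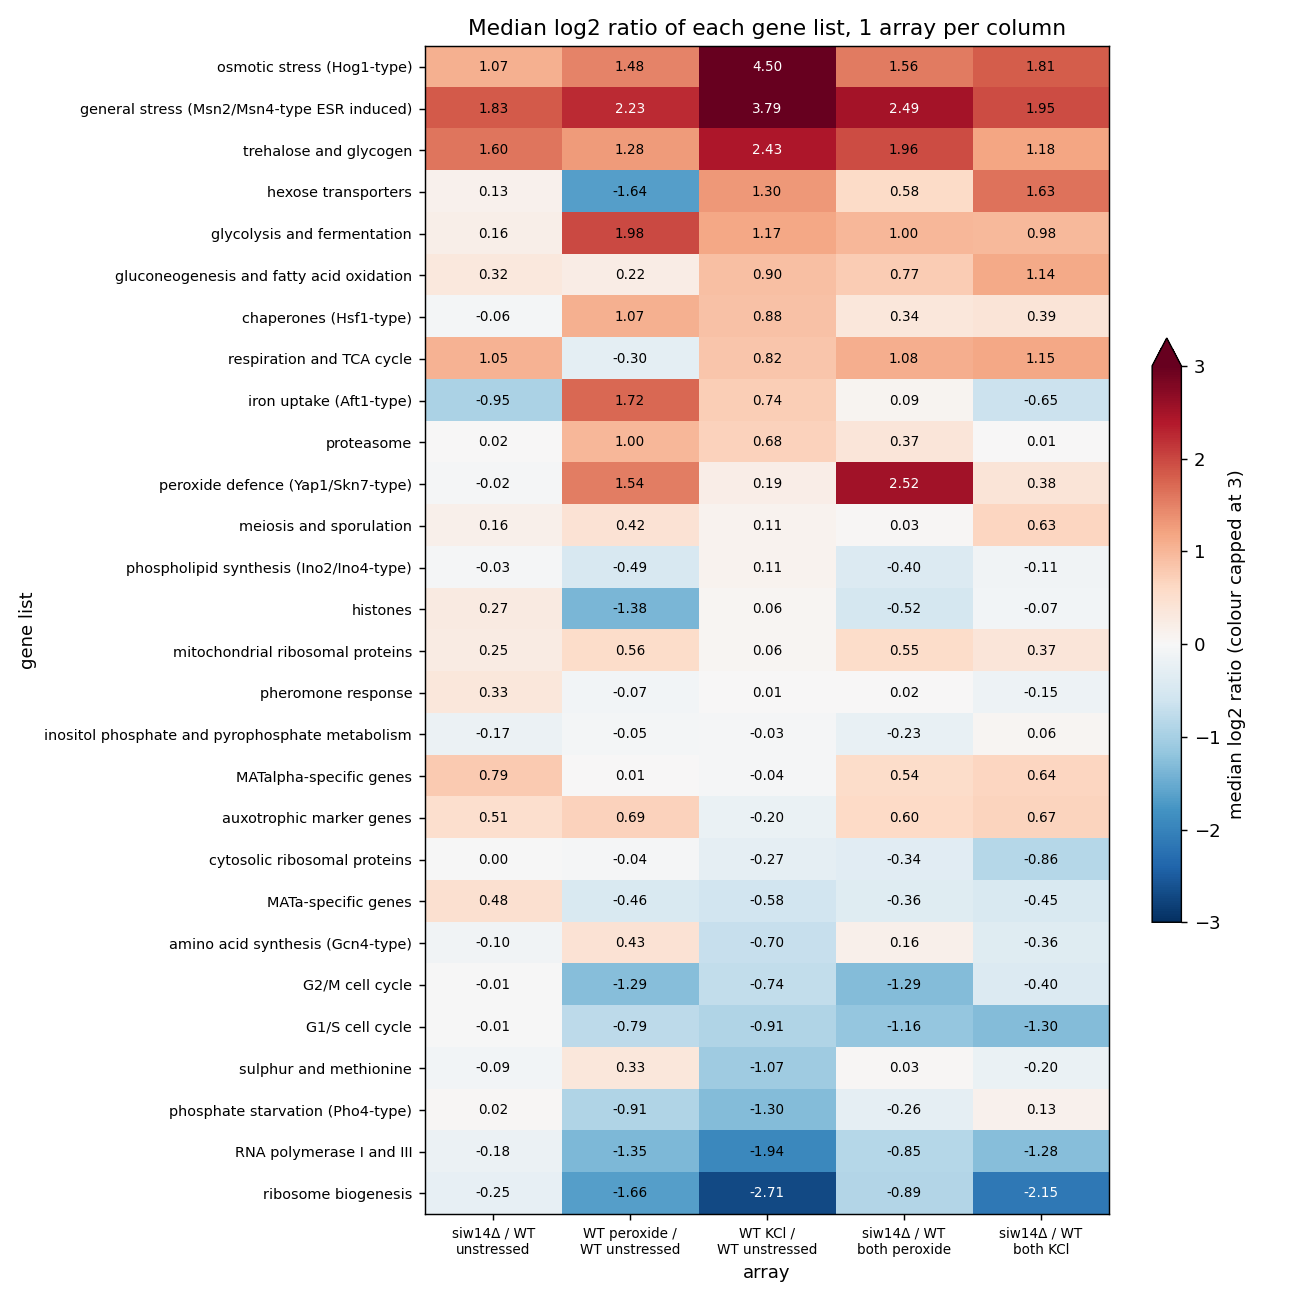
Median log2 ratio of each of the 28 fixed gene lists (rows) on each of the 5 arrays (columns), red above 0 and blue below, with the value in each cell and the colour capped at 3. Osmotic stress genes were highest in wild type in KCl, at 4.50, and ribosome biogenesis genes lowest there, at -2.71.

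The ratio of mutant to wild type in peroxide was set against the same ratio without stress, to see which strain differences came with the stress. This holds only if the wild type on the stressed mutant arrays was itself stressed, which the labels leave uncertain. If it was not, the difference would hold the mutant's own response to the stress. Peroxide defence genes were higher by a median of 2.70 (1.30 to 3.60), with 17 of 20 at least 2-fold higher, led by OYE3 at 6.85, GTT2 at 5.46, FLR1 and the aryl-alcohol dehydrogenase gene AAD4 each at 4.61, GRE2 at 4.21 and AAD6 at 3.60. The ferric reductase gene FRE1 lay at 3.86, the peroxisomal catalase gene CTA1 at 3.85 and iron uptake genes at a median of 1.34. Lower genes were PCL1 at -3.39, YOX1 at -2.82, the mitotic kinase gene CDC5 at -2.47, ILV5 at -2.30, the cyclin genes CLN1 and CLB1 at -2.26 and -2.21, KCC4 at -2.13 and the ribosomal protein gene RPS9A at -2.08. Medians were -1.16 for G1/S genes, -1.26 for G2/M genes, -0.88 for histones, -0.59 for ribosome biogenesis, or -0.29 with each array scaled to its own spread, and -0.30 for cytosolic ribosomal proteins. General stress genes differed by 0.64 (0.39 to 0.78), osmotic stress genes by 0.46 and trehalose and glycogen genes by 0.49. These 3 medians turned to -1.16, -0.52 and -0.84 when each array was scaled to its own spread. Scaling enlarges the ratios of the unstressed mutant, whose spread was narrower, so the difference falls for lists already high there. Their direction thus depends on whether the arrays should be scaled, which is not settled.

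In KCl the corresponding difference, with the same limit, was a median of -1.89 (-2.18 to -1.68) for ribosome biogenesis genes, with 88 of 101 at least 2-fold lower. DHR2 lay at -4.93, SSF1 at -3.99, NOC2 at -3.79, LTV1 at -3.25, NSR1 at -3.21, ZRT1 at -3.24, the glycogen synthase gene GSY1 at -3.16 and URA7 at -3.14. Cytosolic ribosomal protein genes differed by -0.86, G1/S genes by -1.49 and G2/M genes by -0.69. SIP18 lay at 3.05, SNO1 at 2.67, the water channel gene AQY1 at 2.42, the hexose transporter gene HXT5 at 2.30, GPX1 at 2.26, OYE3 at 2.21, YPS5 at 2.17 and the xylitol dehydrogenase gene XYL2 at 2.15. General stress genes differed by a median of 0.14 (-0.12 to 0.33) and did not stand apart, at percentile 96.1, but did at 99.3 among random lists of named genes, and the median turned to -1.45 with arrays scaled to their spread. Osmotic stress genes differed by 0.48 (-0.43 to 0.99), which turned to -0.41 with that scaling.

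Genes higher in the unstressed mutant were often genes higher in stressed wild-type cells, whereas lower genes were seldom shared. Of 335 genes at least 2-fold higher in the unstressed mutant and measured in both, 195 were also at least 2-fold higher in wild type in KCl, where independent lists would share 39.0. In peroxide the count was 164 of 343, with 36.4 for independent lists. For lower genes, 11 were shared with KCl and 16 with peroxide, where independent lists would share 10.2 and 9.96. Across genes, r was 0.450 between the unstressed mutant and wild type in KCl and 0.426 between it and wild type in peroxide. The labels name different wild types for these arrays, for which unchanged RNA gives an r of 0 if dye effects are absent. With no dye swap, a dye effect common to the arrays could raise both r and the overlaps, and it was not simulated. Had the arrays shared their unstressed RNA, unchanged RNA would give 0.493 in simulation, and part of the overlap could come from that. The 2 wild-type stress arrays had r = 0.646, against 0.493 simulated for unchanged RNA if they shared their control RNA. Their covariance was 0.661, and the part that a shared control would add could not be estimated, since no replicate gives the noise. They shared 331 higher genes and 358 lower ones, where independent lists would share 73.2 and 79.1.

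**Figure D3:**
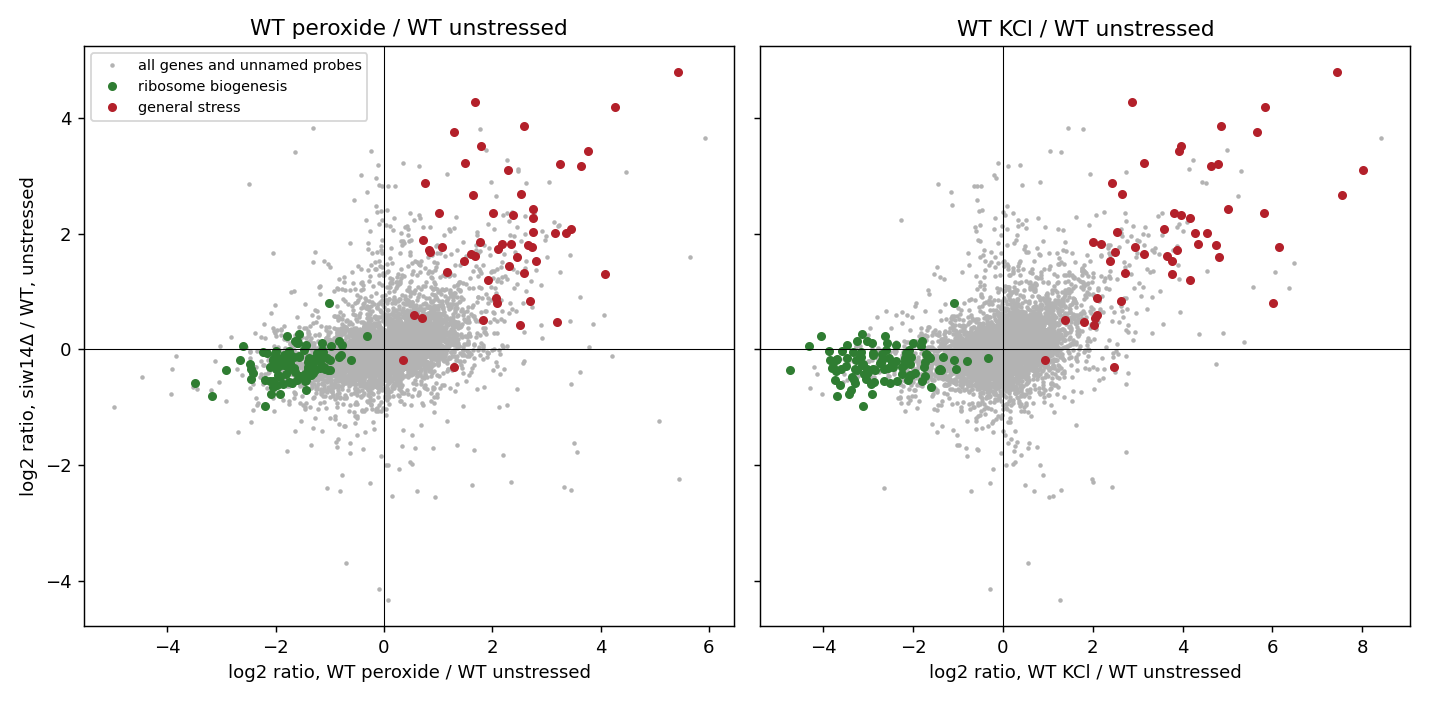
Log2 ratio of each gene in unstressed mutant against wild type (vertical axis) and in wild type under peroxide (left) or KCl (right) against unstressed wild type (horizontal axis), with general stress genes in red, ribosome biogenesis genes in green and all others in grey. General stress genes lie up on both axes, with a median of 1.83 on the vertical, while ribosome biogenesis genes lie far left and near 0 on the vertical, at -0.25.

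The 3 mutant arrays, all with the mutant in Cy5, also resembled each other, to which a dye effect could contribute. Of 5523 genes measured on all 3, 240 were at least 2-fold higher on every one and 28 at least 2-fold lower, ZPS1 and SIW14 among the latter. The unstressed mutant had r = 0.701 with the mutant in peroxide and 0.670 with the mutant in KCl, and those had r = 0.724 with each other. Each stressed mutant array also followed the stressed wild type, with r = 0.663 in peroxide and 0.695 in KCl, although a shared stressed wild-type RNA would by itself give -0.493 in simulation. Across stresses, r was 0.583 between wild type in peroxide and the mutant in KCl and 0.575 between wild type in KCl and the mutant in peroxide.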

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

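The tests of explanations given in this part were all chosen after the results they bear on had been seen. Genes at 2-fold or more in opposite directions drew attention. There were 3 between the unstressed mutant and the mutant in peroxide, all lower without stress and higher in it. The named gene among them was OYE2, an NADPH oxidoreductase gene, at -1.03 and 1.59, and the others were unnamed probes. Between the unstressed mutant and the mutant in KCl there was 1 such gene, GSY1, a glycogen synthase gene, at 2.01 and -1.15. These differences were not tested, since each side is 1 array, and the genes were named after their values were seen.

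Control features outside the yeast comparisons also stood out. The 3 E1A features with a value on every array had medians of 2.08 in the unstressed mutant, 1.75 in the mutant in peroxide and 2.32 in the mutant in KCl, against -0.20 and 0.38 on the wild-type arrays in peroxide and KCl. Over every E1A feature with a value the medians were 1.17 for 7 features in the mutant in peroxide and 0.98 for 9 in the mutant in KCl, with 1 and 3 below 0, and 11 of 23 control features of all kinds lay below 0 in the mutant in KCl. URA3 lay at 3.02, 1.63 and 2.53 on the mutant arrays in the same order, LEU2 at 1.84, 2.24 and 2.10, and the alpha-factor gene MF(ALPHA)2 at 2.28, 2.81 and 2.55. The other MATalpha-specific genes, MF(ALPHA)1, STE3 and SAG1, lay lower, between -0.02 and 1.06 on the mutant arrays. An opposite mating type of the mutant is argued against, since MATa-specific genes had a median of 0.48 in the unstressed mutant (range -0.12 to 1.47, 6 genes) where they would be nearly silent. Marker genes carried by the mutant strain and an upward offset of Cy5 at probes with little target stay open. Of the 6 URA3 and LEU2 values, 1 exceeded the highest E1A feature of its array. The 7 meiosis and sporulation genes with a value on all 3 mutant arrays had a median of 0.42 (range -0.66 to 1.61). Over every member with a value, that list had a median of 0.03 in the mutant in peroxide (13 genes, lowest -3.48). In the mutant in KCl it was 0.63 (11 genes, lowest -0.56). These values decide neither way. The control features below 0 go against an offset of all such probes, but how much target any of them had is not known.

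The stressed mutant arrays resembled the wild type's stress responses across genes (r = 0.663 in peroxide and 0.695 in KCl) although their labels put both strains under stress, and osmotic stress genes as a set were higher in the mutant in KCl too (median 1.81, 8 of 13 at 2-fold or more), though STL1 and GPD1 lay at 0.11 and 0.37 there against 6.68 and 6.02 in wild type. An unstressed wild-type channel with a mutant that reached the wild type's level is argued against in KCl, where osmotic stress genes lay below their wild-type ratios by a median of -2.35 (-4.77 to -1.58, 11 of 13 genes by more than 2-fold). In peroxide, ribosome biogenesis and chaperone genes lay off the wild type's level, which argues against this reading for those 2 lists. General stress genes lay near that level and go with the reading, so it is not settled for all genes. Ribosome biogenesis genes lay above their lowered wild-type ratios by a median of 0.70 (0.64 to 0.91, 97 of 101 genes). Chaperone genes lay below theirs, at -0.80 (-0.96 to -0.63). General stress genes differed by only 0.21 (-0.05 to 0.75), and peroxide defence genes exceeded theirs by 1.71 (0.15 to 3.31, 22 genes). In both stresses single arrays of differently named wild types are compared, and the intervals do not cover cultures. An offset shared by the mutant arrays is argued against as the whole cause, because peroxide minus KCl, where it cancels, still had r = 0.350 across 5604 genes between wild type and mutant arrays. An unstressed wild-type channel with a mutant response of another size, a stronger or longer response of the mutant, and a weaker response of its KCl-treated wild type were not tested and stay open.

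The higher general stress genes in unstressed siw14 cells have 2 technical readings, and both stay open. An upward Cy5 offset at dim probes would lift near-silent genes as well. Meiosis and sporulation genes had a median of 0.16 (-0.66 to 1.44, 7 genes), well below the general stress median of 1.83, but only 7 of 15 had a value. The 3 E1A features with a value on this array, at a median of 2.08, go with the offset, but how much target they had is not known. A mutant culture nearer to glucose exhaustion may also lift HXT6, HXT7 and respiration genes; gluconeogenesis and fatty acid oxidation genes had a median of 0.32 with an interval of -0.79 to 1.5, which decides neither way. Loss of SIW14 acting on Msn2/Msn4 target genes is the biological reading, and with 1 array it cannot be called more than a hypothesis.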

How the results depend on the processing

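No paired analysis was possible because each comparison had 1 array. Values are given in the order unstressed mutant, wild type in peroxide, wild type in KCl, mutant in peroxide, mutant in KCl, with genes higher before genes lower. At 1.5-fold the counts were 660 and 366, 1388 and 1341, 1339 and 1297, 1346 and 1215, and 1275 and 1236. At 3-fold they were 162 and 36, 253 and 268, 320 and 359, 355 and 117, and 277 and 277. Read as natural logarithms, chosen after seeing the data, they were 540 and 228, 1190 and 1158, 1146 and 1098, 1150 and 968, and 1073 and 1007. At 3 robust standard deviations the 4 stressed arrays gave 98 and 48, 171 and 190, 173 and 36, and 126 and 122. How many genes pass follows from the thresholds themselves, but how they divide need not. In the mutant in peroxide the share higher was 60.7% at 2-fold, 75.2% at 3-fold and 82.8% at 3 robust standard deviations. In wild type in peroxide it was 48.5%, 48.6% and 67.1% in that order. On the KCl arrays it was 47.4% in wild type and 50.8% in the mutant at 3 robust standard deviations. Scaled to the median absolute deviation, the unstressed mutant gave 661 and 371 and the mutant in peroxide 306 lower. Among genes with a standard name alone, which are fewer, the unstressed mutant gave 211 and 44, wild type in peroxide 391 and 491, wild type in KCl 414 and 500, the mutant in peroxide 435 and 320, and the mutant in KCl 357 and 462, so 43.6% of the last were higher against 50.9% of all genes past 2-fold. Scaling to the median absolute deviation also turned the difference between mutant arrays with and without stress to -1.16 for general stress, -0.52 for osmotic stress and -0.84 for trehalose and glycogen genes in peroxide, and to -1.45 and -0.41 for general and osmotic stress genes in KCl. It made ribosome biogenesis -0.29 in peroxide and -1.45 in KCl and cytosolic ribosomal proteins -0.72 in KCl. The unstressed mutant's narrower spread makes scaling enlarge its ratios. With chromosome medians subtracted, ribosome biogenesis differed by -0.49 in peroxide, and cytosolic ribosomal proteins lay at -0.26 in the mutant in peroxide. Mitochondrially encoded genes then lay at 0.00 in wild type in KCl and differed by 0.29 in peroxide, both because their own median on each array is subtracted. With scaling instead they differed by 0.14 in peroxide. General stress genes in no other list had a median of 3.10 in the mutant in peroxide. For the other moves the cause was not tested. Of 1096 list values recomputed, 1062 stayed within their interval, but several settings, such as centring, could move values only slightly. Scaling was applied to list values only for the differences between mutant arrays. There, outside the general stress, ribosome biogenesis and cytosolic ribosomal protein lists, 38 stayed, 12 moved and 4 reversed. With random lists from named genes alone, chosen after seeing the data, 9 of 196 list values changed sides. Without signal over background, no limit from dim probes could be set.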

Other observations

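The tests and gene groups in this part were chosen after the data had been seen. Several zinc-regulated genes were low in siw14 cells with and without stress, in a group put together after ZPS1 and ADH4 had been seen among the lowest genes. Of its 10 genes, 4 were at least 2-fold lower in the unstressed mutant, 5 in the mutant in peroxide and 4 in the mutant in KCl, with medians of -0.90 (-2.45 to 0.23), -1.06 (-2.70 to 0.23) and -0.75 (-3.45 to 0.42). ZPS1 lay at -3.69, -3.07 and -3.45 on those arrays and ADH4 at -2.45, -2.49 and -2.21, while ZAP1, the gene of the zinc-responsive activator, lay at -1.16, -2.70 and -1.50. In wild-type cells the group's median was -0.86 in peroxide, with ZRT1 at -2.32, and -0.13 in KCl.

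Mitochondrially encoded genes were low in wild-type cells in peroxide, at a median of -2.04 (-3.53 to -1.32), with 11 of 13 at least 2-fold lower. COX1 lay at -2.47, COX3 at -2.04 and COB at -1.73, while OLI1 lay at 0.43. The median was -0.43 in wild-type cells in KCl, -0.31 in the unstressed mutant, -1.02 in the mutant in peroxide and 0.03 in the mutant in KCl. The arrays measured polyadenylated RNA, and mitochondrial transcripts of yeast lack long poly(A) tails.

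Added on the log scale, wild-type stress and the stressed mutant ratio would place the mutant under stress against unstressed wild type. This needs the differently named wild types to be alike and the wild type on the stressed mutant arrays to have been stressed. The labels leave the latter uncertain, and without it the sums given here would not be the mutant's level. For ribosome biogenesis genes in KCl this sum had a median of -4.98 (-5.39 to -4.38, 101 genes), a 31.5-fold lower level after 20 min. From the wild type's unstressed level this would need an mRNA half-life of 4.02 min with no synthesis. The unstressed mutant already lay at a median of -0.25, so the fall in the mutant itself would be somewhat smaller. The sum for general stress genes had a median of 5.96 in KCl and 4.75 in peroxide. The robust standard deviations were 0.76 and 0.73 on the wild-type stress arrays and 0.76 and 0.74 on the stressed mutant arrays, against 0.38 for the unstressed mutant.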
